A study of Homo sapiens with 8 samples.

How the data were processed

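SK-BR-3 is an established human breast cancer line with amplified ERBB2. The microRNAs mir-141 and mir-200c lie next to each other on chromosome 12 and had been removed, singly or together, with TALENs, pairs of designed nucleases that cut a chosen DNA sequence. The 8 libraries formed 4 groups of 2: wild type, mir-141 knockout, mir-200c knockout and double knockout. Each group had 1 library in each of 2 experimental sets, and each knockout group was a different clone in each set. In set 1 the clones were numbers 23 (mir-141), 11 (mir-200c) and 55 (double), and in set 2 they were 10, 29 and 61. Clone and set could therefore not be told apart within a group. P-values and standard errors (SE) rest on the spread between the 2 sets, pooled over the groups and moderated across genes. They do not measure the spread between the 2 clones of 1 group.

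Per the labels' protocols, mRNA was selected with oligo(dT) beads and fragmented, adaptors were ligated to both ends of the fragments, and the libraries were read on an Illumina HiSeq. Per the submitters' processing notes, TopHat2 (version not given in the sources used here) and the build GRCh37.p10 were used. How reads were counted, scaled and filtered is not given in the sources used here.

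The values the authors deposited are log2 ratios of each knockout clone to the wild type of the same set, in 6 columns for 9245 RefSeq mRNA entries with 9241 distinct symbols. Each column averaged to about 0. Expression levels, counts and library depth could not be read from these log2 ratios, so the depth of each library is unknown, no interval or floor that needs it was given, and no filter or weighting by level was possible. A gene with few reads and a gene with many therefore carry the same weight. Columns of samples outside the series numbered 0.

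The design fixed before the data were examined assumed expression values for each library. With ratios in their place, each wild type was set to 0 and the ratio of a clone stood for its library, which builds the experimental set into every comparison. Because the labels name a shared experimental set and every ratio was taken within it, the set pairs the libraries, and a fit on levels without it could not be made. The 6 ratios taken as independent values served as the alternative without the block. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all genes: a model of the 4 groups with 3 residual degrees of freedom, and an additive model of both losses with 4. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. On simulated data for 9245 genes with the spread of the deposited ratios, 74% of 100 genes changed by a log2 of 1 were called in the mir-141 knockout, 78% in the double knockout and 98% for loss of mir-141 across both backgrounds. All of those changed by 2 were called, with 12, 15 and 15 false calls. Each simulated change was placed on the same row in both sets. These shares therefore hold only if a row holds the same gene in both, which is in doubt here.

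Of 31 gene lists fixed before the data were examined, 28 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way, served as alternatives. For single clones, where no test can be made, the median of a list is given with its percentile among 10000 random lists of the same size. These lists could not be matched on expression level, and the percentile describes the libraries only.

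Annotation came from GENCODE release 29 (GRCh38), and all coordinates are on that build. Of the entries, 9222 were matched to a gene, 9000 of them by RefSeq accession. Seed sites of 7 or 8 bases were searched in the longest annotated 3' UTR of 9205 entries. This gave 1347 genes with sites of mir-141-3p only, 1181 with sites of mir-200c-3p only, 1042 with both and 5635 with neither, and 4 seeds of microRNAs from other tissues served as controls. The score of a library was the mean ratio of site genes minus that of genes with neither site. It was tested by exact two-sided permutation of the labels within each set, which has 36 arrangements and cannot give a p below 0.0556. Shifts of single clones were taken against random lists matched on 3' UTR length in 20 bins. All heptamers present in at least 50 genes were ranked in the same way. Chromosome blocks were runs of 20 neighbouring genes whose median lay beyond the most extreme window of 200 shuffled gene orders. Both procedures were tested on simulated data: site genes raised by 0.1 gave a matched shift of 0.0896, and a block raised by 0.5 was found, with 0 blocks found where none was added.

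The rule for named genes, fixed before the data were examined, asked for an adjusted p under 0.05, an average level at or above the median and separation of all libraries. Levels were not measured and 0 genes passed the threshold, so it left 5 of 11 genes fixed by name and, for each list past its threshold, up to 4 members with the smallest p in the direction of the list. Some members chosen by this rule are left out of the text. To describe set 1, the 10 highest and 10 lowest genes of each comparison were added after their values were seen. For loss of a microRNA these were ranked by the weaker of its effects in both backgrounds. Alternatives tried were quantile normalization, median centring, robust empirical Bayes, smaller fits, each set alone, each library left out, other site and 3' UTR definitions, other window sizes, and realigned rows of set 2. Count-based alternatives (other size factors, count tests, filters on low counts, pseudocounts, a subset by level) could not be applied to ratios. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for everything outside the linear models.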

Results

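Messenger RNA of 8 SK-BR-3 libraries was compared: wild-type cells and clones lacking mir-141, mir-200c or both, in 2 experimental sets with 1 library per group in each. The study asked how mRNA levels change when these microRNAs are removed. Both belong to the mir-200 family, which is known for repressing inducers of the mesenchymal state, and their seed sequences differ at a single base. The values were log2 ratios of a clone to the wild type of its set for RefSeq mRNA entries, of unknown depth. The SD of a column across genes lay between 0.31 (mir-141 knockout of set 1) and 0.46 (double knockout of set 2).

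The ratios of the 2 sets were unrelated across genes. Within set 1 the Pearson correlations between clones were 0.502, 0.709 and 0.630, and within set 2 they were 0.506, 0.568 and 0.697. Between sets the mean over 9 pairs was 0.00488, and no pair exceeded 0.0105 in size. Ratios of 2 unchanged clones to 1 shared wild type correlate at 0.50 (0.453 to 0.543) in simulations that give all libraries of a gene the same spread. The correlation of both single knockouts in set 1, 0.502, lay in that range, so it cannot tell shared changes from the shared control. Pairs with a double knockout lay above it. The covariance of both single knockouts in set 1, 0.0666, was above the simulated mean of 0.0497 and the highest simulated value of 0.0604. Genes next to each other on a chromosome had similar ratios in set 1 (mean Spearman 0.0916) and not in set 2 (0.00192). Genes are not independent replicates, and these correlations describe the libraries. Set 2 values are given below as listed beside a gene's name, and they may stand beside the wrong names (weighed under Other observations). If so, each mean, SE, gene call, list test and site score over both sets combines different genes. Calls of 0 genes would then say little about the knockouts.

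**Figure D1:**
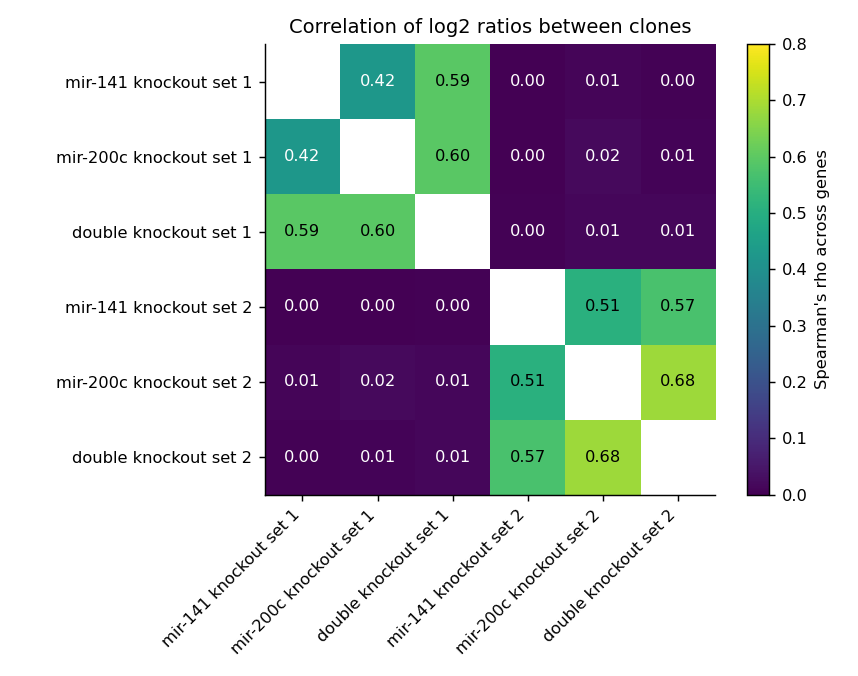
Spearman correlation across genes of the log2 ratios of each pair of the 6 knockout clones, as colour and number. Pairs within a set reach up to 0.684, whereas pairs from different sets lie near 0, at most 0.0203.

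The targeted microRNAs themselves were not analysed here, so the knockouts were not checked in these libraries. EPCAM, an epithelial adhesion molecule, had ratios of 0.08, 0.06 and −0.05 in the mir-141, mir-200c and double knockout of set 1 and 0.06, −0.03 and 0.11 in set 2. ERBB2, the amplified receptor of this line, had −0.18, −0.14 and −0.14 in set 1 and 0.15, 0.04 and −0.08 in set 2. Among neighbours of the microRNA locus on chromosome 12, C12orf57 had 0.17, −0.03 and 0.12 in set 1 and 0.18, 0.04 and 0.29 in set 2. The phosphatase gene PTPN6 (12, 6946468 to 6961316) had 0.24, 0.30 and 0.14 in set 1 and was listed at 0.80, 0.73 and 1.18 in set 2. The transcriptional corepressor gene ATN1 had 0.19, −0.17 and 0.06 in set 1 and was listed at −0.82, −0.67 and −0.93 in set 2. ZEB1, ZEB2, CDH1, VIM, PHB2 and EMG1 were not analysed here.

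After knockout of mir-141, the clone of set 1 had 54 genes above a log2 ratio of 1 and 52 below −1. FBP1, which encodes the gluconeogenic enzyme fructose-1,6-bisphosphatase (chromosome 9, 94603133 to 94640249), was lowest at −6.08, and WDR20, a cofactor of deubiquitinating enzymes (chromosome 14, 102139503 to 102224847), was highest at 4.76. High ratios were also seen for NBL1, a secreted BMP antagonist (3.20), OLFM4, a secreted glycoprotein (2.76), CGA, the shared subunit of glycoprotein hormones (2.41), PIP, a secretory protein of apocrine cells (2.07), GPR110 (2.07), TRAF6, a signalling ubiquitin ligase (1.88), and S100A7, psoriasin (1.75). Low ratios were seen for KHNYN (−4.68), PARVB, an actin-binding parvin (−3.82), NSMAF, an adaptor of neutral sphingomyelinase (−3.57), BASP1 (−2.70), GATA2, a transcription factor (−2.64), NCCRP1 (−2.61), SPDYC (−2.55) and MUC5B, a gel-forming mucin (−2.19). FAM86B2 (3.24), HIST1H2AD (3.09) and ORM1 (−2.06) have near-identical copies and are uncertain. In the mir-200c and double knockout of set 1, TRAF6 had 2.07 and 1.93, PIP 1.69 and 1.95 and GPR110 2.20 and 1.22. By contrast, CGA had −0.01 and 2.06 and S100A7 −0.43 and 2.05 there. The clones of set 1 share 1 wild type, so a gene shifted alike in all of them cannot be ascribed to loss of mir-141. KHNYN lies in a block of chromosome 14 that was lower in set 1.

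Of the 106 genes beyond 1 in that clone, 52.8% had the same sign in set 2 and 1 lay beyond 1 in the same direction there. FBP1 was listed at 0.15 and WDR20 at 0.00 in set 2. Over both sets, limma called 0 genes (smallest adjusted p 0.998), with 248 at an unadjusted p under 0.05 where chance gives 462.25. Immediate early genes, which respond within minutes to growth signals, rose as a list (camera, adjusted p = 0.0481, 14 of 16 members above 0). The adjusted p was 0.942 with an estimated correlation. The count of lists was 0 after median centring, 0 without the wild type of set 1 or either mir-141 clone, and 3 without the wild type of set 2. Members with the smallest p were DUSP5 (0.40 ± 0.16, mean of 2 clones ± SE of the pooled fit), KLF2 (0.53 ± 0.35), JUNB (0.24 ± 0.16) and DUSP4 (0.31 ± 0.20).

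After knockout of mir-200c, the clone of set 1 had 157 genes above 1 and 98 below −1. WDR20 was highest (5.11), followed by NT5E, the ecto-nucleotidase CD73 (3.39), MYL9, a myosin regulatory light chain (3.20), OLFM4 (2.98), GBP1, an interferon-induced GTPase (2.5), CHST15, a sulfotransferase (2.45), SYK, a tyrosine kinase (2.25), and DNAJC12 (2.22). FBP1 was lowest (−7.01), followed by GATA2 (−4.09), CA8 (−2.69), TNFRSF18 (−2.56), DTD2 (−2.49), C11orf86 (−2.31) and NCCRP1 (−2.26). FAM86B2 (2.93), HIST1H2AD (2.70), HIST1H2BH (−4.60), ORM1 (−2.50) and ORM2 (−2.75) are uncertain because of near-identical copies.

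In set 2, MYL9 was listed at 0.22, NT5E at 0.13, GATA2 at 0.35 and FBP1 at 0.09, and 47.1% of the 255 genes beyond 1 in set 1 kept their sign. Limma called 0 genes (smallest adjusted p 0.793, 499 at p under 0.05). With camera, 4 lists passed. The list of actin cytoskeleton and motility genes rose (adjusted p = 0.00298, 24 of 29 members above 0), among them the focal adhesion protein ZYX (0.65 ± 0.16), the kinase ROCK1 (0.47 ± 0.17) and the actin-severing protein CFL2 (0.54 ± 0.21). The antigen presentation list rose (0.00931, 9 of 10), with the immunoproteasome subunit PSMB8 (1.12 ± 0.37), the peptide transporter TAP1 (0.55 ± 0.28) and HLA-C (0.63 ± 0.36). Interferon-stimulated genes rose (0.0428, 10 of 13), with OAS3 (0.58 ± 0.22), IFITM1 (0.43 ± 0.17), ISG15 (0.54 ± 0.23) and IFIH1 (0.33 ± 0.23). Cell cycle genes fell (0.0101, 28 of 34 below 0), with the mitotic kinases AURKA (−0.50 ± 0.19) and PLK1 (−0.42 ± 0.17), the replication helicase subunit MCM4 (−0.37 ± 0.14) and the centromeric histone CENPA (−0.39 ± 0.15). For all 4 lists the adjusted p was 0.665 with an estimated correlation, and without the wild type of set 1 or the mir-200c clone of set 1, 0 lists passed.

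In the double knockout of set 1, 141 genes were above 1 and 69 below −1. WDR20 (4.51), OLFM4 (4.43), CYP4B1, a cytochrome P450 (3.04), MYL9 (3.01), LCN2, the iron-sequestering lipocalin (2.48), NT5E (2.45), NBL1 (2.30) and STAC2 (2.17) were high, as were the uncertain HIST1H2AD (4.35) and FAM86B2 (3.15). FBP1 (−8.51), MUC5B (−3.72), NSMAF (−3.62), GATA2 (−3.28), IGFBP2, which binds insulin-like growth factors (−3.27), SNRPN, an imprinted splicing gene (−3.20), KHNYN (−3.12), P2RX5, an ATP-gated channel (−2.86), SPDYC (−2.27) and PARVB (−2.24) were low. In set 2 OLFM4 was listed at 0.16, MUC5B at −0.28 and IGFBP2 at 0.57, and 48.1% of the 210 genes beyond 1 kept their sign.

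Over both double knockout clones limma called 0 genes (smallest adjusted p 0.740, 581 at p under 0.05), and 4 lists passed with camera. Immediate early genes rose (adjusted p = 0.00233, 15 of 16 above 0), with the phosphatases DUSP1 (0.43 ± 0.17) and DUSP5 (0.37 ± 0.16) and the transcription factors JUN (0.74 ± 0.40) and KLF6 (0.50 ± 0.27). NF-kB inflammatory genes rose (0.0463, 8 of 8), with the adhesion molecule ICAM1 (0.72 ± 0.28), LCN2 (1.13 ± 0.56), TNF (0.34 ± 0.26) and IER3 (0.26 ± 0.23). Genes of nuclear oxidative phosphorylation fell (0.0245, 23 of 30 below 0), with NDUFB5 (−0.67 ± 0.16), COX5B (−0.48 ± 0.14), ATP5C1 (−0.51 ± 0.18) and COX7B (−0.44 ± 0.19). Cell cycle genes fell (0.0345, 25 of 34), with AURKA (−0.62 ± 0.19), the checkpoint kinase BUB1B (−2.15 ± 0.75), MCM6 (−0.49 ± 0.18) and MCM4 (−0.35 ± 0.14). For all of them the adjusted p was 0.794 with an estimated correlation, and without the double knockout or the wild type of set 1, 0 lists passed. Adjusted over the list alone, 1 gene passed in this comparison, MYOF of the YAP and TEAD targets (1.07 ± 0.24, adjusted p = 0.0426 with limma), against 0.740 over all genes. Each list was adjusted by itself, with no correction for the number of lists and comparisons tried, so such a pass can arise by chance.

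Loss of mir-141 across both backgrounds compares clones with and without mir-141 at the same state of mir-200c. In set 1, CGA (2.24), S100A7 (2.11), STAC2 (2.12), OLFM4 (2.10), PLTP, a phospholipid transfer protein (1.60), PLXDC2 (1.54), GTSF1 (1.37), PDE4B, a cyclic AMP phosphodiesterase (1.37), and CX3CR1, a chemokine receptor (1.25), were highest when genes were ranked by the weaker background, and the values are means of both. HIST1H2AD (2.37) met the same rule and is uncertain. The lowest were KHNYN (−4.36), FBP1 (−3.79), PARVB (−3.14), NSMAF (−3.10), P2RX5 (−2.01), MUC5B (−1.97), PODXL (−1.35), CD40 (−1.28), ACSF3 (−1.21) and COL18A1 (−1.18). A gene shifted alike in all clones of set 1, which share 1 wild type, carries that shift into the means of both losses. FBP1 had −6.08, −7.01 and −8.51 in the mir-141, mir-200c and double knockout, so its change in the mir-200c background was smaller than its mean. The same holds for OLFM4, MUC5B and HIST1H2AD. Over both sets limma called 0 genes (smallest adjusted p 0.901, 476 at p under 0.05). Immediate early genes rose (camera, adjusted p = 0.000257, 14 of 16 above 0), with ETV4 (0.69 ± 0.26), JUNB (0.26 ± 0.10), DUSP4 (0.33 ± 0.13) and IER3 (0.40 ± 0.17), and the adjusted p was 0.560 with an estimated correlation. Cholesterol biosynthesis genes fell (0.0442, 17 of 19 below 0), with HMGCS1 (−0.42 ± 0.13), LSS (−0.23 ± 0.09), INSIG1 (−0.31 ± 0.15) and DHCR7 (−0.18 ± 0.11), and their adjusted p was 0.559 with an estimated correlation. Without the double knockout or the wild type of set 1, 0 lists passed.

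Loss of mir-200c across both backgrounds was ranked in the same way, again with means of both backgrounds, and was highest in set 1 for MYL9 (2.71), OLFM4 (2.33), GBP1 (2.10), CLDN1, a tight junction protein (1.79), CYP4B1 (1.75), LCN2 (1.68), KRT17, a basal keratin (1.66), ZSWIM4 (1.58) and ANXA3 (1.37), with the uncertain HIST1H2AD (1.98). The lowest were FBP1 (−4.72), IGFBP2 (−1.78), MUC5B (−1.75), PCP4 (−1.28), FGFR3, a growth factor receptor (−1.12), S100A1 (−1.09), ATP11A (−1.07), C2orf76 (−0.92) and LINGO1 (−0.82), with the uncertain HIST1H2BH (−2.79). FBP1, OLFM4, MUC5B and HIST1H2AD were extreme for loss of mir-141 too, and a shift shared by all clones of set 1 enters their means here as well. Limma called 0 genes over both sets (smallest adjusted p 0.541, 821 at p under 0.05). Adjusted over the list alone, ZYX of the actin list (0.51 ± 0.11, limma adjusted p = 0.0479) and CORO1A of the blood cell genes (−0.40 ± 0.11, 0.0182 over the 3 measured members, too few for a list test) passed, each at 0.541 over all genes. The number of lists tried was again not corrected for.

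With camera, 7 lists passed for loss of mir-200c. Actin genes rose (adjusted p = 0.00459, 24 of 29 above 0), with CFL2 (0.51 ± 0.13), ROCK1 (0.39 ± 0.11) and MYL9 (1.43 ± 0.49) beside ZYX. Antigen presentation genes rose (0.0139, 9 of 10), with TAP1 (0.37 ± 0.20), PSMB8 (0.56 ± 0.32) and HLA-B (0.43 ± 0.25). NF-kB inflammatory genes rose (0.0190, 7 of 8), with LCN2 (0.77 ± 0.38), TNF (0.34 ± 0.18), ICAM1 (0.36 ± 0.20) and TNFAIP3 (0.33 ± 0.19). YAP and TEAD targets rose (0.0358, 11 of 15), with GADD45A (0.54 ± 0.14), MYOF (0.53 ± 0.16), F3 (0.39 ± 0.15) and WWC1 (0.26 ± 0.11). Epithelial markers rose (0.0460, 20 of 33), with OCLN (0.39 ± 0.09), PRSS8 (0.27 ± 0.11) and TJP3 (0.22 ± 0.12). Cell cycle genes fell (0.0139, 28 of 34 below 0), with AURKA (−0.41 ± 0.13), BUB1B (−1.56 ± 0.51), CCNB2 (−0.28 ± 0.12) and KIF11 (−0.22 ± 0.10). Oxidative phosphorylation genes fell (0.0427, 22 of 30), with COX5B (−0.29 ± 0.09), COX5A (−0.37 ± 0.14), ATP5C1 (−0.31 ± 0.13) and NDUFA4 (−0.21 ± 0.09). For all 7 the adjusted p was 0.540 with an estimated correlation. The count was 0 without the wild type or the mir-141 clone of set 1, 1 without the double knockout and 2 without the mir-200c clone of that set, and 11, 11 and 12 without the mir-200c clone, the double knockout and the wild type of set 2.

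In single clones of set 1, mesenchymal markers had a median of 0.932 in the mir-200c knockout and 0.674 in the double knockout (percentile 100 among 10000 random lists in both), and 0.0368 in the mir-141 knockout (73.6). Among them the actin regulator CALD1 had 0.37, 1.32 and 0.95 in the mir-141, mir-200c and double knockout, FSTL1 had 0.25, 1.01 and 1.06, the RNA-binding QKI had −0.19, 0.93 and 0.67, and the smooth muscle protein TAGLN had −0.22, 2.08 and −0.41. Basal breast markers had medians of 0.400, 0.322 and 0.453 (percentiles 100, 98.9 and 99.9), with KRT14 at 0.52, 1.00 and 0.95. The oestrogen receptor programme had −0.0100, −0.328 and −0.192 (49.5, 1.20 and 6.37), with the trefoil peptide TFF1 at −0.18, −2.17 and −0.55. Of the lists too small to test, fibroblast genes were measured for COL5A2 (0.91, 0.69 and 1.28), COL5A1 (−0.29, 1.29 and −0.09) and COL1A1 (−0.11, −0.41 and −0.15), and blood cell genes for LCP1 (−0.13, 1.05 and −0.44), CD68 (0.52, −0.48 and 0.40) and CORO1A (−0.01, −0.54 and −0.48). In set 2 as listed, mesenchymal markers had medians of −0.130, −0.231 and −0.237. Only 11 of the 32 genes on that list were measured. Over both sets it did not pass with camera in the mir-200c knockout (adjusted p = 0.175), the double knockout (0.785) or for loss of mir-200c (0.307). Of 28 lists, 2, 12 and 11 had medians outside the central 95% of random lists in the clones of set 1 and 2, 4 and 0 in those of set 2, where chance gives 1.40.

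**Figure D2:**
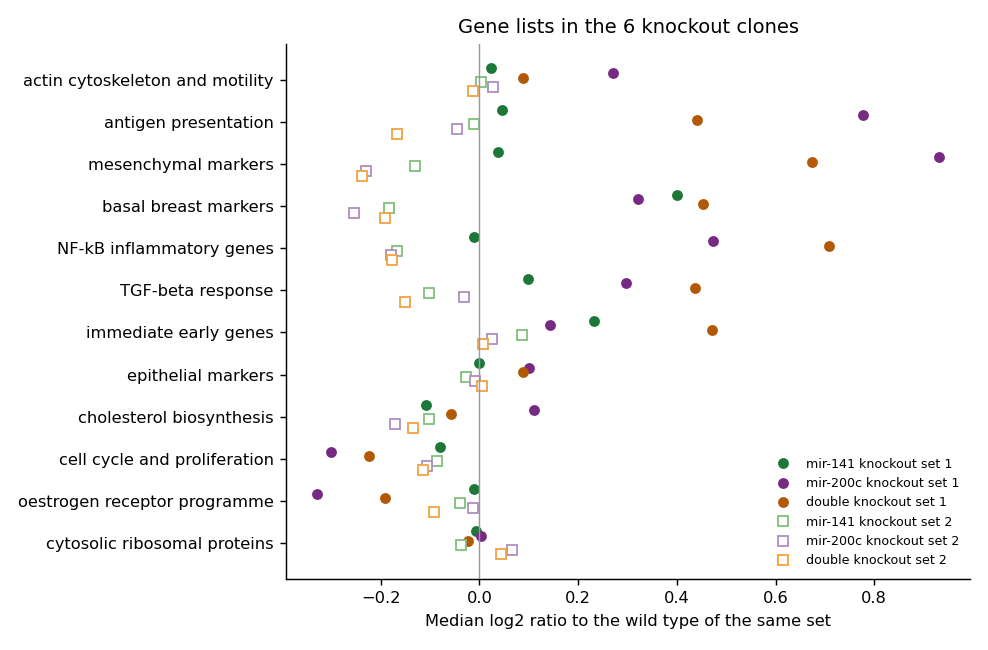
Median log2 ratio to the wild type of the same set for 12 gene lists (filled circles, set 1, and open squares, set 2; colour marks the clone). Mesenchymal markers reach 0.932 in the mir-200c knockout of set 1 and −0.231 in that of set 2.

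Limma called 0 genes for the interaction (smallest adjusted p 1.00, 157 at p under 0.05), and 0 genes were called in both single knockouts, where simulated unchanged groups against the same wild types share 0.05. At p under 0.05 in the same direction, 61 genes were shared, against 107.8 in those simulations and 6.65 for independent lists. The correlation across genes of the additive losses was 0.111 (covariance 0.00456), where simulations without effects ranged from −0.0534 to 0.0711 (mean covariance −1.05e-06). These simulations gave all libraries of a gene the same spread, which by itself sets the expected covariance to 0. Libraries of unequal spread would move it without any effect, so a value above the range does not show that both losses move the same genes. In set 1 alone it was 0.0331. Without the mir-141 clone it was −0.0934 (set 1 left out) and −0.0448 (set 2), and without the mir-200c clone −0.00173 and −0.0943. It was 0.290 and 0.217 without the wild type of set 1 and of set 2, and 0.328 and 0.224 without the double knockout. With 1 library left out, the losses share another library of that set. That library enters with opposite signs if a single knockout is missing and with the same sign otherwise. These signs are what shared error alone would give, and do not show a reversal. Large ratios were shared between clones of set 1: 28 genes lay above 1 in both single knockouts and 26 in all 3 clones, and 19 lay below −1 in all 3. All 3 ratios share 1 wild type, so a gene high or low there alone is shared too.

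Genes with mir-200c-3p sites had higher ratios in the clones of set 1 that lack mir-200c. Genes with an 8mer site (208 genes) lay 0.124 above length-matched random lists in the mir-200c knockout (percentile 99.99) and 0.0876 above in the double knockout (99.95), and 0.00364 above in the mir-141 knockout (56.9). In set 2 as listed, the shifts were 0.0106, 0.0337 and −0.00794. Each lay within the range of the control seeds with 8mer sites there. That range was −0.0261 to 0.0162 in the mir-200c knockout, −0.0293 to 0.0520 in the double knockout and −0.0516 to 0.00604 in the mir-141 knockout. With 7mer and 8mer sites together (1181 genes), the shift was 0.0209 in the mir-200c knockout of set 1 (97.05) and 0.00959 in its double knockout (82.64), and 0.0198 for loss of mir-200c (99.45). Of 16139 heptamers, the mir-200c site AGTATTA ranked 1 and CAGTATT ranked 2 for loss of mir-200c in set 1. In set 2 as listed they ranked 726 and 38. Over both sets the difference in score for loss of mir-200c was 0.0326, with 0.0499 in set 1 and 0.0153 in set 2 (exact permutation p = 0.0556, the smallest this design allows). Unlike the shifts above, this score was not matched on 3' UTR length. Ratios for this loss rose with that length in set 1 (Spearman 0.106), so part of the score and its p can come from length. Camera on the same genes gave p = 0.173, and 0.0420 with an estimated correlation. For loss of mir-141, the scores of the mir-200c site genes differed by 0.00328 (exact p = 0.889).

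For genes with mir-141-3p sites, the difference in score was 0.0109 for loss of mir-141 (exact p = 0.444) and 0.00887 for loss of mir-200c (0.556), with camera p of 0.485 and 0.927. The 258 genes with 8mer sites lay 0.00152 above matched lists for loss of mir-141 in set 1 (percentile 53.6). For that loss the mir-141 site CAGTGTT ranked 114 among heptamers and AGTGTTA 3543 in set 1, and 7091 and 10425 in set 2 as listed. Literature targets of mir-200b and mir-200c had a median of 0.197 for loss of mir-200c in set 1 (percentile 100 among random lists), with the actin crosslinker FLNA at 0.37, 1.38 and 1.08 and the small GTPase RND3 at 0.02, 1.08 and 0.88 in the mir-141, mir-200c and double knockout, while those of mir-141 and mir-200a had 0.0643 for loss of mir-141 (96.5). In set 2 as listed, these medians were −0.0293 (36.4) and −0.0723 (12.2). Over both sets the mir-200b and mir-200c targets did not pass for loss of mir-200c (camera, adjusted p = 0.0737, and 0.540 with an estimated correlation).

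**Figure D3:**
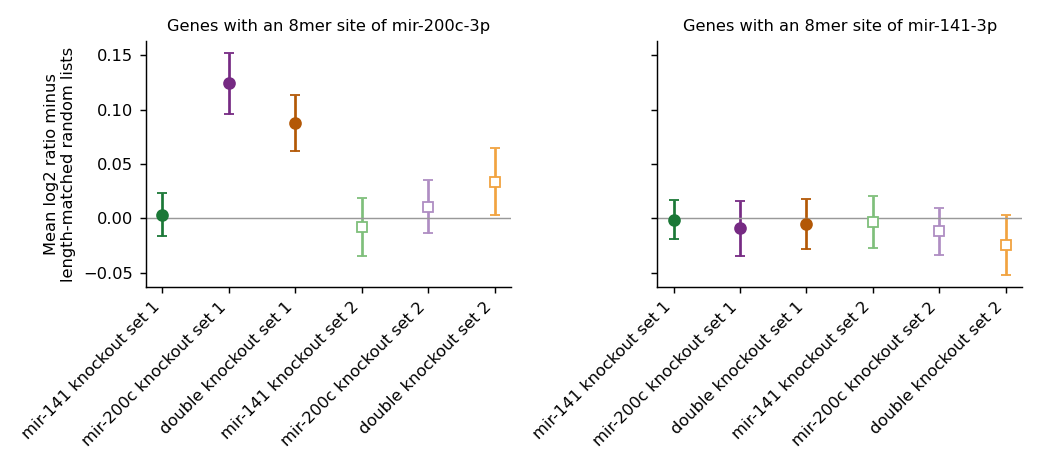
Mean log2 ratio of genes with an 8mer site of mir-200c-3p (left) or mir-141-3p (right) minus that of length-matched random lists, per clone (filled, set 1, and open, set 2). Bars show 1 SD of the random lists, and the mir-200c and double knockouts of set 1 stand at 0.124 and 0.0876 on the left.

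Neighbouring genes were shifted together in all 3 clones of set 1. On chromosome 18, from 35241030 to 80147523, the median of 59 genes was 0.51 in the mir-141 knockout, 0.00 in the mir-200c knockout and 0.77 in the double knockout (block SD 0.45), and 53, 30 and 55 of them were above 0. On chromosome 14, from 24209583 to 35277614, the medians of 32 genes were −0.14, −0.33 and −0.30. Genes of chromosome 22 from 35257452 to 39522685 had −0.46 in the mir-200c knockout and −0.38 in the double knockout, and genes of chromosome 6 from 139028682 to 151391548 had 0.44 in the mir-200c knockout. In the double knockout, genes of chromosome 13 from 19633681 to 27256691 had −0.42. The number of blocks was 2, 6 and 8 in the clones of set 1 and 0 in each clone of set 2 as listed. With windows of 10 genes it was 3, 1 and 5 in set 1 and 1, 0 and 0 in set 2, and with windows of 40 it was 2, 2 and 5 in set 1 and 0 in each clone of set 2.

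**Figure D4:**
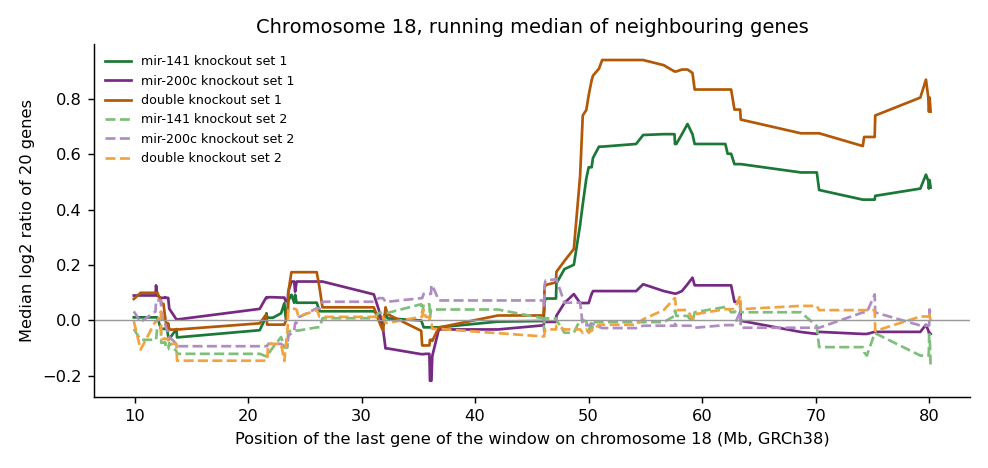
Running median of the log2 ratio of 20 neighbouring genes along chromosome 18 (GRCh38, in Mb at the last gene of each window) for each of the 6 clones. The mir-141 knockout and the double knockout of set 1 rise beyond the middle of the long arm, to window medians of 0.71 and 0.94, and the other lines stay between −0.22 and 0.15.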

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

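Median centring, robust empirical Bayes, each set alone, realignment of set 2, the 3' UTR of the deposited transcript and windows of 10 or 40 genes were chosen after seeing the data. Without replicate block, with the 6 ratios as independent values, limma again called 0 genes in each knockout and camera 1, 3 and 3 lists, against 1, 4 and 4 with the set built in. Centring scores within set as a replicate block left the mir-200c score at 0.0326. It could not do otherwise, since libraries with and without the loss are balanced within each set. Quantile normalization, median centring, robust empirical Bayes and the smaller fits also gave 0 genes. All list calls were lost, 0 in every comparison, with an estimated correlation and with fry. With median centring the mir-141 knockout had 0 lists. For loss of mir-200c, set 1 alone gave 13 lists and set 2 alone 0, and for loss of mir-141 set 2 alone gave 0. The score of mir-141 site genes reversed in set 2 alone, to −0.000598 for loss of mir-141 and −0.00477 for loss of mir-200c. Adjusted for 3' UTR length and GC, that for loss of mir-200c reversed to −0.00353, and that of mir-200c site genes for loss of mir-141 to −0.000895. The cause was not tested.

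With set 2 realigned on ratio size, limma called 1 gene in the mir-200c knockout, 2 for loss of mir-141 and 1 for the interaction, and camera called 6, 10 and 13 lists in the mir-141, mir-200c and double knockout and 7 for loss of mir-141, where shuffled tables gave at most 1, 11, 7 and 3. With an estimated correlation all of these were 0.

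Leaving out each library in turn, genes called ranged from 0 to 1 in the mir-141 knockout, 0 to 1 in the mir-200c knockout, 0 to 2 in the double knockout, 0 to 0 for either loss, 0 to 1 for the interaction and 0 to 1 for both single knockouts. The correlation of the losses ranged from −0.0943 to 0.328, but with a library left out the losses share error, which alone moves it either way. Lists ranged from 0 to 3, 0 to 10 and 0 to 10 in the mir-141, mir-200c and double knockout, and from 0 to 2 and 0 to 12 for loss of mir-141 and mir-200c. Scores of mir-141 site genes ranged from 0.00251 to 0.0161 and from 6.12e-05 to 0.0137 for loss of mir-141 and mir-200c, and those of mir-200c site genes from −0.00853 to 0.0143 and from 0.0267 to 0.0391. Count tests, other size factors, filters on low counts, pseudocounts and a subset by level were not run, since ratios allow none of them. Unknown depth leaves open how far counting error sets the spread.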

Other observations

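All tests weighed below were chosen after the results were seen, as were the realignment of set 2, the splits of the libraries and the limits that decide each test. In set 1, replication-dependent histone genes had a median effect of 0.405 for loss of mir-141 (percentile 100 among random lists) and −0.409 in the mir-200c knockout (0.22), and their family members share sequence. CAV1, a membrane scaffold protein, had ratios of 1.07, 0.68 and 2.00 in the mir-141, mir-200c and double knockout, and KRT16 had 0.41, 1.74 and 0.97. Cytosolic ribosomal proteins, an abundant class, had medians of −0.00675, 0.00285 and −0.0239.

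The ratios of the 2 sets were unrelated even in size, and values of set 2 may stand beside the wrong gene names, with an offset that drifts along the table. Offsets between −18 and 17 positions, found from ratio size alone with signs unused, raised the mean Spearman correlation of signed ratios of the same genotype from 0.0121 to 0.209, against −0.00866 to 0.0134 in 20 shuffled tables. Chromosome neighbours in the mir-141, mir-200c and double knockout of set 2 then correlated at 0.0403, 0.0342 and 0.0355 (Spearman, signed ratios). As listed they had −0.00901, 0.0134 and 0.00137, and shuffled gene orders of the listed values reached at most 0.0282, 0.0287 and 0.0324. The realigned values stayed below the set 1 mean of 0.0916. MYL9 then took 2.69, 1.04 and 3.45 and OLFM4 −0.22, 5.12 and 6.97 in the mir-141, mir-200c and double knockout of set 2. The alignment matches rows on size, so large sizes at these genes were favoured by the choice of offsets and only the signs were free. FBP1 (0.24, 0.05 and 0.23) and WDR20 (0.08, 0.38 and −0.18) stayed near 0 in set 2, and the mesenchymal markers had medians of 0.378, 0.125 and −0.128 there, unlike set 1, while the mir-200c heptamer CAGTATT ranked 38 of 16139 for loss of mir-200c in set 2 as listed, which wrong names would not predict. These offsets are an estimate, from 1 of 13 settings tried with the signed correlations in view, after circular shifts and sorted orders had failed; the others gave 0.174 to 0.231 and 5 of them were higher. Counting noise with correct names is argued against by ribosomal protein genes. In set 1 their median ratio size was 0.58, 0.57 and 0.53 of that of all genes, below random lists (lower limits 0.69, 0.69 and 0.67). In set 2 as listed it was 0.86, 1.03 and 0.83 (mean 0.910), above the lower limits of 0.68, 0.69 and 0.69. After realignment on size it fell to 0.77, 0.70 and 0.73, still above them. The alignment matches rows on size and these genes are small in set 1, so a fall was favoured and decides nothing. Noise beside wrong names stays open. The mean correlation of ratio size between sets was 0.0125, where redrawn values with the gene spread of set 1 gave 0.415. That argues against different biology with correct names only if both sets share this gene spread. Clones whose changes fall on different genes need not share it, so different biology stays open.

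The second pattern is the higher ratio of mir-200c site genes after loss of mir-200c in set 1. Length of the 3' UTR as the whole cause is argued against by a percentile of 99.45 among length-matched lists; a first version of this test, on the lower of both clones, gave 82.64 and would have left length open, so this evidence is weak, while 8mer genes alone lay 0.104 above matched lists. Chromosome blocks are argued against by a shift of 0.0219 over 1120 site genes outside them. The seed heptamer ranked 2 among all heptamers, which may reflect loss of mir-200c. In set 2 realigned on size, 8mer genes lay 0.0652 above matched lists for this loss (percentile 99.9), and realigned on size and mean ratio 0.0343 (95.5). The second alignment matches signed mean ratios to set 1, so its value is not independent of set 1. Shuffled tables aligned that way reached mean Spearman correlations of 0.129 to 0.165 with set 1.

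The third pattern is the shifted blocks of neighbouring genes in set 1. After adjustment for GC content and 3' UTR length, the chromosome 18 block of the double knockout kept a median of 0.77, and its genes without a mir-141 site had 0.77, which argues against both composition and direct targeting. A copy number difference between the clones and the wild-type cells could not be tested: 93.2% of these genes were above 0, but the block was picked for its high medians, and the share with the same sign was 69.4% on chromosome 8. Realigned on size, the whole block had 0.29 in the double knockout and −0.19 in the mir-141 knockout of set 2, and the search found a block within it in that double knockout (59327823 to 80046397, 0.59) and 1 on chromosome 22 in the mir-200c knockout (35257452 to 38075701, −0.33), beside 2 in the mir-141 knockout on chromosomes 1 and 12 that set 1 lacked.

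Other splits of the 8 libraries into 4 and 4 did not exclude chance for the lists: 14 of 33 splits gave at least the 2 lists for loss of mir-141 (highest other 9), and 6 gave at least the 7 lists for loss of mir-200c (highest other 11). For genes the real counts were 0, so all 33 splits had to give as many (highest other 12 and 6), which says nothing about chance. After realignment on size, 7 lists passed for loss of mir-141 where 20 shuffled tables gave at most 3, and 8 for loss of mir-200c where they gave up to 12. With an estimated correlation 0 passed in either.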
